A study of Mus musculus with 69 samples.

How the data were processed

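RNA of the hippocampus of 69 male mice was sequenced, 1 library per animal, in 8 groups of genotype (Cdh13 knockout or wildtype), rearing (separated or control) and age (P22 or P66), from 2 breeding cohorts. Per the labels' protocols, pups were separated for 3 h a day from P1 to P14 and weaned at P22, and the hippocampus was taken from frozen brain slices. Per the submitters' processing notes, FastQC 0.11.4, cutadapt 1.16, edgeR and limma 3.34.9 were used; the aligner, the counting tool and the genome build are not given in the sources used here. The values are raw counts of reads per gene, which the authors deposited without normalization as 1 table with a column per animal.

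The table as held ends on chromosome 8. It gave 9930 complete gene records, all protein-coding, of chromosomes 1 to 7 and the first part of chromosome 8, and 1 record broken at its end was left out. Of the gene identifiers 9885 (99.55%) were found in GENCODE M21, and 96.5% of these had the same chromosome, start and end there, so positions are given on GRCm38. Genes beyond this part, among them Cdh13, the sex-linked and the mitochondrial genes, were not analysed here. A check of the genotype labels by the level of Cdh13 was therefore not made, and of the 40 gene lists the 3 on neighbours of Cdh13, mitochondrial transcripts and sex-linked genes had no gene. Library totals are sums over the held part, not the full depth. They lay between 11.3 and 16.4 M counts (M, mega), and 116 genes had no count in any library. Within groups 272 pairs of libraries were checked for duplicates; chi-square per degree of freedom ran from 4.60 to 91.9, so no pair differed by counting error alone. No paired analysis was possible because the animal numbers run separately within cohort and rearing group, so that a number shared by different groups names different animals. The labels used here name no litters, so animals were treated as independent. Separation was applied to litters, so its standard errors and p-values are too small if littermates resemble each other.

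Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the groups (minimum count 10, minimum total 15), which left 7036 genes at P22, 7001 at P66 and 7131 over all libraries, and were normalized by TMM. Each age was fitted by edgeR quasi-likelihood with a term for each group and for cohort. The contrasts were knockout minus wildtype and separated minus control, each averaged over the other factor, their interaction, and the effects within each genotype and rearing group. Age, and its interactions with genotype, rearing and both, were tested in 1 fit of all 69 libraries. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Without any effect an unadjusted p under 0.05 is expected on average in 352 genes at P22, 350 at P66 and 357 over all libraries. Fold changes are on the log2 scale with their standard error (SE). Levels in the text are counts per M counts (CPM) of the held part, on TMM-scaled library sizes. Counts of animals on 1 side compare each animal with the median of the reference animals that share its other factor.

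Gene lists for cell types, pathways and neighbouring tissues were fixed before the data were examined, as were the contrasts, the thresholds, the rule for named genes and all alternatives not marked as later. Of the 40 lists 34 had at least 5 tested genes. They were tested with camera of limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2), again with the correlation estimated from the data, and with fry. Benjamini-Hochberg adjustment was over the lists of a contrast. The named genes are the 10 with the largest rise and the 10 with the largest fall among genes past the threshold with a mean log2 CPM of at least 0, the 5 with the smallest p where fewer than 5 passed, and up to 4 called or 2 uncalled members of each list described. A few genes that this rule names are not reported here. Spata5 and its partner genes, and the comparison of Hspa5, Dbp and Ciart across single groups, were chosen after their values were seen. Detection was tested on simulated data made from these libraries with known changes of 1.2, 1.5 and 2-fold. In them genes varied independently of each other and many changed at once. The shares recovered may therefore be higher than in the real libraries.

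The alternatives were DESeq2 1.42.0, limma-voom, RLE normalization, no count filter, a stricter filter (at least 1 CPM in 7 libraries), no cohort term, each cohort alone, scores of choroid plexus and oligodendrocyte genes as covariates, an adjusted p under 0.1, all libraries in 1 fit, and leaving out each library. Later additions, made after the data were seen, were a clock score as covariate at P66 and leaving out libraries whose choroid plexus score was more than 2 (log2) away from the median. That last setting was first limited to libraries above the median and left out none, so it was widened to both sides. Scores are means of log2 CPM over a list. For the clock score Arntl, Npas2 and Clock were subtracted from Dbp, Ciart, Per2 and Per3. Group comparisons of scores used two-sided permutation tests within cohort. Each count of genes was set against 100 regroupings of the animals within cohort, the real one included. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.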

Results

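Hippocampal RNA of male mice was measured by RNA sequencing at P22, the day of weaning, and at P66. Mice lacking Cdh13, the gene of the adhesion molecule T-cadherin, and wildtype mice came from litters that were either separated from the dam for 3 h a day from P1 to P14 or handled and otherwise left with it (control). Each of the 69 libraries came from 1 animal, and the animals belonged to 2 breeding cohorts. At P22 there were 8 control wildtype, 11 separated wildtype, 9 control knockout and 10 separated knockout animals. At P66 the numbers were 7, 10, 7 and 7 in the same order. The count table analysed here ends on chromosome 8 and holds 9930 protein-coding genes of chromosomes 1 to 8. Cdh13 itself and the genes of the remaining chromosomes were not analysed here, so the genotype labels were taken from the sample descriptions without a check on the level of Cdh13. Within this part the libraries held 11.3 to 16.4 M counts (M, mega; median 13.3 M). Group means ran from 12.7 ± 0.386 M (SD, n = 7) in control wildtype animals at P66 to 13.8 ± 1.35 M (SD, n = 7) in separated knockout animals at P66. The most abundant gene took 0.775% of the counts and the top 10 took 4.64%.

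Age and the amount of choroid plexus RNA were the main differences between the libraries. The first principal component held 19.8% of the variance and followed age (r² = 0.856). The next components held 11.5% and 9.73%, and both were led by genes of the choroid plexus, the tissue that makes cerebrospinal fluid, such as Kcnj13, Folr1 and Aqp1.

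To test whether the loss of Cdh13 changes the hippocampus at weaning, knockout and wildtype animals were compared at P22 with environment averaged. No gene passed, and the changes of the genes with the smallest p were small. Mfap1b differed by a log2 fold change of -0.08 ± 0.0232 (SE, 19 knockout against 19 wildtype animals), Mllt3 by -0.13 and Micalcl by -0.19, while Serping1, which encodes the complement C1 inhibitor, differed by 0.23 ± 0.0743 and Zfp628 by 0.15. All 5 had an adjusted p = 0.832. Ribosomal protein genes were slightly higher as a group, with a mean log2 change of 0.04 over 33 tested genes and 32 of them positive (camera, adjusted p = 0.0049). None of the 33 passed by itself, and the list had an adjusted p = 0.933 with an estimated correlation. The lists nearest to the function of T-cadherin were not called: mean changes were -0.02 for cadherins and catenins (adjusted p = 0.867), -0.07 for adiponectin signalling (adjusted p = 0.376), -0.06 for GABA receptors (adjusted p = 0.159) and -0.02 for glutamate receptors (adjusted p = 0.997). In the same order 7 of 19, 5 of 10, 10 of 19 and 11 of 22 listed genes were tested, so these results cover only part of each list. By edgeR 0 of 7036 genes passed and 289 had an unadjusted p under 0.05, fewer than the 352 expected without any effect. DESeq2 and limma-voom also called 0. In simulated data with the same group sizes edgeR recovered 98.5% of genes changed 1.5-fold and 76.1% of those changed 1.2-fold. Genes varied independently there, so the shares may be lower in the real libraries.

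Maternal separation was compared with control rearing at P22 to test for an early effect of the stress. Genes induced by glucocorticoids, the hormones of the stress response, had negative changes in 8 of 8 tested members (mean log2 change -0.15), among them Hif3a at -0.42 ± 0.161 and Mertk at -0.17 ± 0.0671 (SE, 21 separated against 17 control animals). Myelin genes went the other way in 11 of 11 members (mean 0.16; Ppp1r14a 0.19, Cldn11 0.18). Choroid plexus genes were negative in 11 of 11 (mean -0.33; F5 -0.47, Kl -0.30) and ribosomal protein genes positive in 33 of 33 (mean 0.04). None of these members passed by itself, neither over all genes nor adjusted over the list alone. Camera called 10 lists, these 4 with adjusted p = 0.00027, 2.54e-05, 0.000595 and 0.000514 in that order. With an estimated correlation the same 4 had adjusted p = 0.262, 0.555, 0.562 and 0.601. The other 6 were interneuron genes (mean -0.04, adjusted p = 0.000706; Reln -0.14, Lhx6 -0.12), microglia (-0.06, 0.00592; Mrc1 -0.24, Cd163 -0.30), cholesterol synthesis (0.05, 0.00647; Pmvk 0.08, Insig1 0.11), meninges (-0.12, 0.0334; Igf2 -0.24, Slc13a4 -0.27), thalamus and habenula (0.12, 0.0334; Lef1 0.17, Nexn 0.28) and inflammation (0.07, 0.0428; Il1a 0.28, B2m 0.08). Their adjusted p with an estimated correlation lay between 0.418 and 0.562. In edgeR 0 genes passed, and 217 had an unadjusted p under 0.05, fewer than the 352 expected without any effect. The smallest adjusted p was 0.881 (Inpp5d -0.17 ± 0.0414, G6pd2 0.55 ± 0.136). DESeq2 and limma-voom called 0 as well.

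Whether separation acts differently in knockout animals at P22 was asked with the interaction, the effect in knockout minus that in wildtype animals. Choroid plexus genes had the largest shift, with a mean log2 change of -1.42 and 11 of 11 members negative (Steap1 -1.58 ± 0.543, Aqp1 -1.47 ± 0.613). Ependymal genes, which line the ventricles, shifted with them (mean -0.72, 6 of 6 negative; Cfap126 -1.04, Mia -1.01). Neuronal lists had positive means: glutamate receptors 0.16 (Grin2b 0.37, Grm5 0.27), potassium and sodium channels 0.11 (Kcna2 0.24, Scn2a 0.24), axon guidance 0.13 (Ntng1 0.49, Plxna2 0.18) and dentate gyrus 0.16 (C1ql3 0.36, Calb1 0.30). Myelin genes averaged -0.36 (Ppp1r14a -0.45, Gsn -0.45), ribosomal protein genes -0.11 with 33 of 33 negative, nuclear genes of oxidative phosphorylation -0.07, and endothelial genes 0.12. Camera called these 10 lists, from adjusted p = 2.84e-08 for choroid plexus to 0.0238 for glutamate receptors and axon guidance; with an estimated correlation all 10 lost the call, with adjusted p between 0.508 and 0.687. Adjusted over the list alone, 3 ependymal genes were negative and 1 axon guidance gene positive; over all genes none was. By edgeR 0 genes passed, and 596 had an unadjusted p under 0.05, where 352 are expected without any effect. DESeq2 and limma-voom called 0. The genes with the smallest p were Naaa (-0.25 ± 0.0576), Usp13 (0.31 ± 0.0735) and Bdh2 (-0.84 ± 0.196), each with an adjusted p = 0.295, and Trh had 2.57 (adjusted p = 0.584), or 1.47 without control wildtype C1-32. Bdh2 averaged 2.91 ± 0.492 CPM (SD, n = 8) in control wildtype, 4.25 ± 0.918 (n = 11) in separated wildtype, 4.16 ± 0.763 (n = 9) in control knockout and 3.42 ± 0.806 (n = 10) in separated knockout animals.

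In adult animals, at P66, chaperones of protein folding were lower in knockout than in wildtype animals. Hspa5, the main chaperone of the endoplasmic reticulum (ENSMUSG00000026864.13, chromosome 2, 34771970 to 34777547), fell by 0.45 ± 0.0806 on the log2 scale, a fold of 1.36 (SE, 14 knockout against 17 wildtype animals, adjusted p = 0.012). Pdia3, a disulfide isomerase of the same compartment (ENSMUSG00000027248.13, chromosome 2, 121413775 to 121438687), fell by 0.24 ± 0.0405 (adjusted p = 0.00961), and Hsph1, a cytosolic heat-shock protein (ENSMUSG00000029657.15, chromosome 5, 149614287 to 149636376), fell by 0.18 ± 0.0357 (adjusted p = 0.0244). Garem2, an adaptor of growth factor signalling (ENSMUSG00000044576.6, chromosome 5, 30105161 to 30118378), rose by 0.24 ± 0.0433 (adjusted p = 0.012). Hspa5, Pdia3 and Garem2 lay on that side in 14 of 14 knockout animals and Hsph1 in 12. Hspa5 averaged 529 ± 75.4 CPM (SD, n = 7) in control wildtype and 411 ± 45.4 (n = 7) in control knockout animals, and 764 ± 148 (n = 10) and 528 ± 81.3 (n = 7) in the separated groups. Garem2 averaged 34.6 ± 1.09 CPM (n = 7) in control wildtype and 41 ± 3.25 (n = 7) in control knockout animals.

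The fall extended over the fixed list of heat-shock and unfolded-protein genes at P66. All 7 tested members had lower values in knockout animals (mean log2 change -0.22); 2 fell over all genes, and 7 fell adjusted over the list alone. Camera gave an adjusted p = 1.35e-10, and an adjusted p = 0.0187 with an estimated correlation; fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, gave an adjusted p = 0.000566. Glucocorticoid-induced genes had a mean of -0.28 and a median of -0.10, 0 called over all genes and 2 lower adjusted over the list alone (camera adjusted p = 0.0224; Lcn2 -2.27 ± 0.713, Sult1a1 -0.27 ± 0.089). That list had an adjusted p = 0.7 with an estimated correlation, and Lcn2 was 0.37 in cohort 1. Ribosomal protein genes averaged 0.03 (camera adjusted p = 0.00843, adjusted p = 0.988 with an estimated correlation). Cadherins and catenins (-0.13, adjusted p = 0.15), adiponectin signalling (-0.04, 0.826), GABA receptors (-0.04, 0.826) and glutamate receptors (-0.06, 0.631) were not called. As at P22, only part of each of these lists was tested.

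The P66 genotype test by edgeR called 4 of 7001 genes, 1 higher and 3 lower. An unadjusted p under 0.05 was found for 585, where 350 are expected without any effect. In cohort 1 alone, with 9 wildtype and 8 knockout animals, 0 genes passed, and in cohort 2 alone 96 did. Cohort 2 held 4 control wildtype, 4 separated wildtype, 4 control knockout and only 2 separated knockout animals. Hspa5 differed by -0.19 in cohort 1 and -0.80 in cohort 2, Pdia3 by -0.11 and -0.39, Hsph1 by -0.12 and -0.28, and Garem2 by 0.23 and 0.26. DESeq2 called 16 genes, among them all 4. With a clock score as covariate 0 genes passed, and without separated wildtype C1-55 the count was 8. Leaving out each library in turn, Hsph1 kept its call in 15 of 31 fits and the other 3 in all.

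The same chaperones were higher in separated than in control animals at P66. Hspa5 rose by 0.45 ± 0.0814 on the log2 scale, a fold of 1.37 (SE, 17 separated against 14 control animals, adjusted p = 0.0107), and was higher in 17 of 17 separated animals. Pdia4 rose by 0.37 ± 0.0783 (adjusted p = 0.0346), Pdia3 by 0.21 ± 0.0413 and Hsph1 by 0.18 ± 0.0366 (both adjusted p = 0.0247). Pdia3 averaged 436 ± 28.4 CPM (SD, n = 7) in control and 508 ± 38.5 (n = 10) in separated wildtype animals, and 373 ± 32.8 (n = 7) and 429 ± 34.1 (n = 7) in knockout animals. All 7 tested members of the heat-shock and unfolded-protein list were higher (mean 0.23); 3 rose over all genes and 7 adjusted over the list alone (camera adjusted p = 4.46e-10, adjusted p = 0.024 with an estimated correlation, fry adjusted p = 0.000513).

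Genes of the circadian clock also changed with separation at P66. Dbp, an output gene of the clock (ENSMUSG00000059824.12, chromosome 7, 45705088 to 45710203), fell by 0.51 ± 0.0942 on the log2 scale (adjusted p = 0.0133; lower in 16 of 17 animals). Ciart, a repressor within the clock (ENSMUSG00000038550.10, chromosome 3, 95878503 to 95882251), fell by 0.46 ± 0.0795 (adjusted p = 0.00909; 17 of 17). Arntl, which encodes BMAL1, the activator that opposes it, rose by 0.16 ± 0.0368 (adjusted p = 0.0467; 16 of 17). Dbp averaged 128 ± 17.5 CPM (SD, n = 7) in control and 99.1 ± 18.2 (n = 10) in separated wildtype animals, and 173 ± 16 (n = 7) and 112 ± 31.9 (n = 7) in knockout animals. Of the circadian list 1 gene rose and 2 fell over all genes, and 1 rose and 3 fell adjusted over the list alone (mean -0.12, camera adjusted p = 0.0288, adjusted p = 0.284 with an estimated correlation). In cohorts 1 and 2 the change was -0.58 and -0.36 for Dbp, -0.53 and -0.32 for Ciart and 0.14 and 0.15 for Arntl. The labels used here give no hour of collection.

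**Figure D1:**
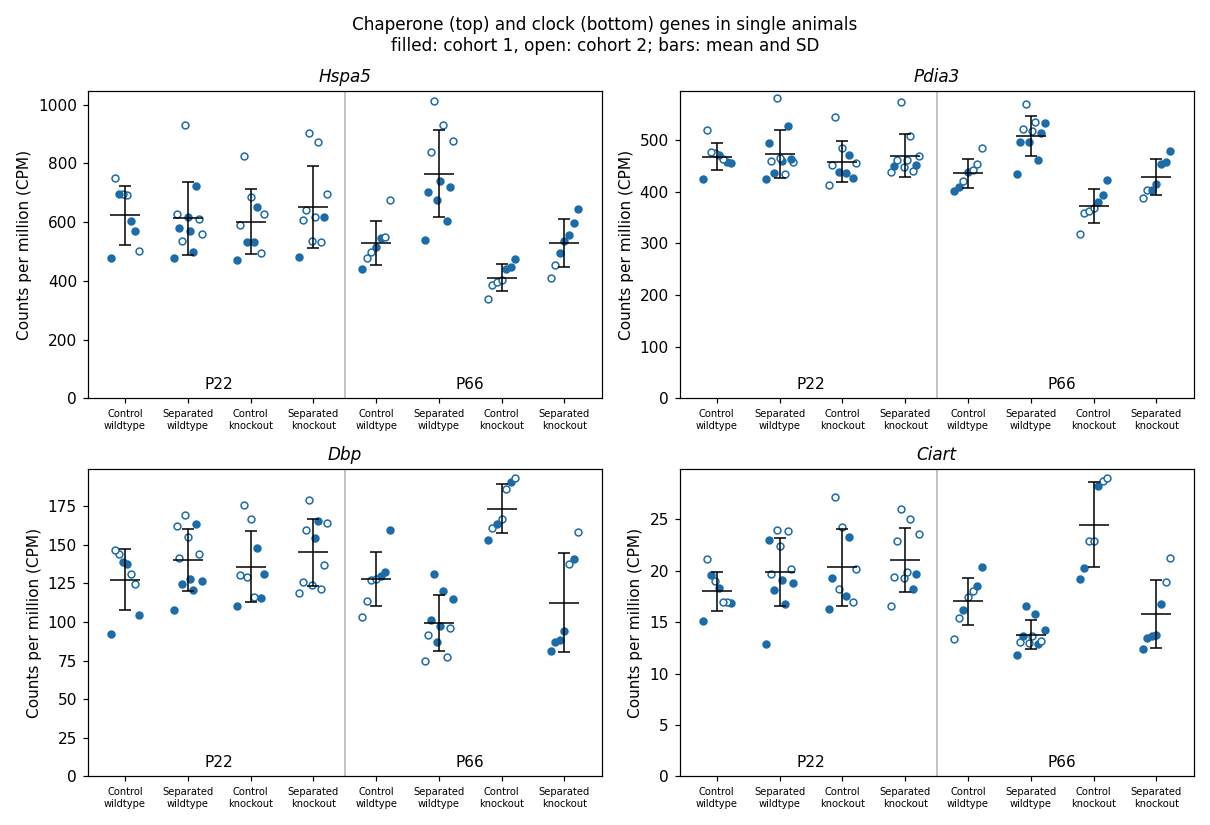
Level in counts per M counts (CPM) of Hspa5, Pdia3, Dbp and Ciart in each of the 69 animals by group and age, with filled points for cohort 1, open points for cohort 2, and bars for the group mean and SD. At P66 Hspa5 averages 529 CPM in control and 764 in separated wildtype animals, and 411 and 528 in control and separated knockout animals.

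Among other genes that changed with separation at P66, Kctd21 (0.19), Mlec (0.15), Nif3l1 (0.15) and Ppp2r2c (0.10) rose. Fbn1, which encodes the matrix protein fibrillin, fell by 0.32 ± 0.0719, and Zfp46 (-0.30), Ccdc142 (-0.28), Ankrd16 (-0.23), Leng8 (-0.21), Rsrp1 (-0.20), Snapc4 (-0.19) and Pla2g4e (-0.18) fell too, with adjusted p between 0.0346 and 0.0498 and 15 to 17 of 17 animals on that side. Camera also called stress axis genes (mean 0.11, adjusted p = 0.037; Oxtr 0.26, Fkbp4 0.15; 2 higher adjusted over the list alone), immediate early genes (0.13, 0.0211; Klf4 0.34, Nr4a3 0.16), myelin (0.15, 11 of 11 positive, 0.00294; Ermn 0.27, Gpr37 0.14), oxidative phosphorylation (0.04, 0.000246; Ndufb2 0.08), ribosomal proteins (0.03, 0.00268), cholesterol synthesis (0.05, 0.0279; Fdps 0.12, Cyp51 0.09) and choroid plexus (-0.57, 11 of 11 negative, 0.0279; F5 -0.36, Steap1 -0.33). F5 and Steap1 were 0.11 and 0.30 in cohort 2, and single libraries moved them to between -0.65 and -0.20 and between -0.52 and -0.16. The separated wildtype libraries C2-42 and C1-57 had the lowest choroid plexus scores, -3.55 and -2.69 from the median of all 69. With an estimated correlation these 7 had adjusted p = 0.231 for the stress axis and 0.785 to 0.882 for the others.

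By edgeR separation changed 26 of 7001 genes at P66, 9 higher and 17 lower. An unadjusted p under 0.05 was found for 855, where 350 are expected without any effect. Cohort 1 alone gave 0 genes and cohort 2 alone 2, and the log2 change of Hspa5 was 0.36 and 0.46 in them, that of Pdia3 0.18 and 0.21, and that of Hsph1 0.20 and 0.14. DESeq2 called 98 genes, among them all 26, while 9 genes passed without the low-count filter and 4 with choroid plexus and oligodendrocyte scores in the model. With a clock score as covariate 0 passed, where Dbp, Ciart and Arntl are part of the score and lose their call by construction; without the libraries far from the median in choroid plexus signal 7, and without the cohort term 41. The count ranged from 3, without control wildtype C1-6, to 75, without separated knockout C2-84, over fits that each left out 1 animal. Of 31 such fits, the call was kept by Hspa5 and Ciart in all, by Dbp in 30, Pdia3 in 25, Hsph1 in 23, Pdia4 in 16, Fbn1 in 11 and Arntl in 8, and by the other genes named in 6 to 15.

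**Figure D2:**
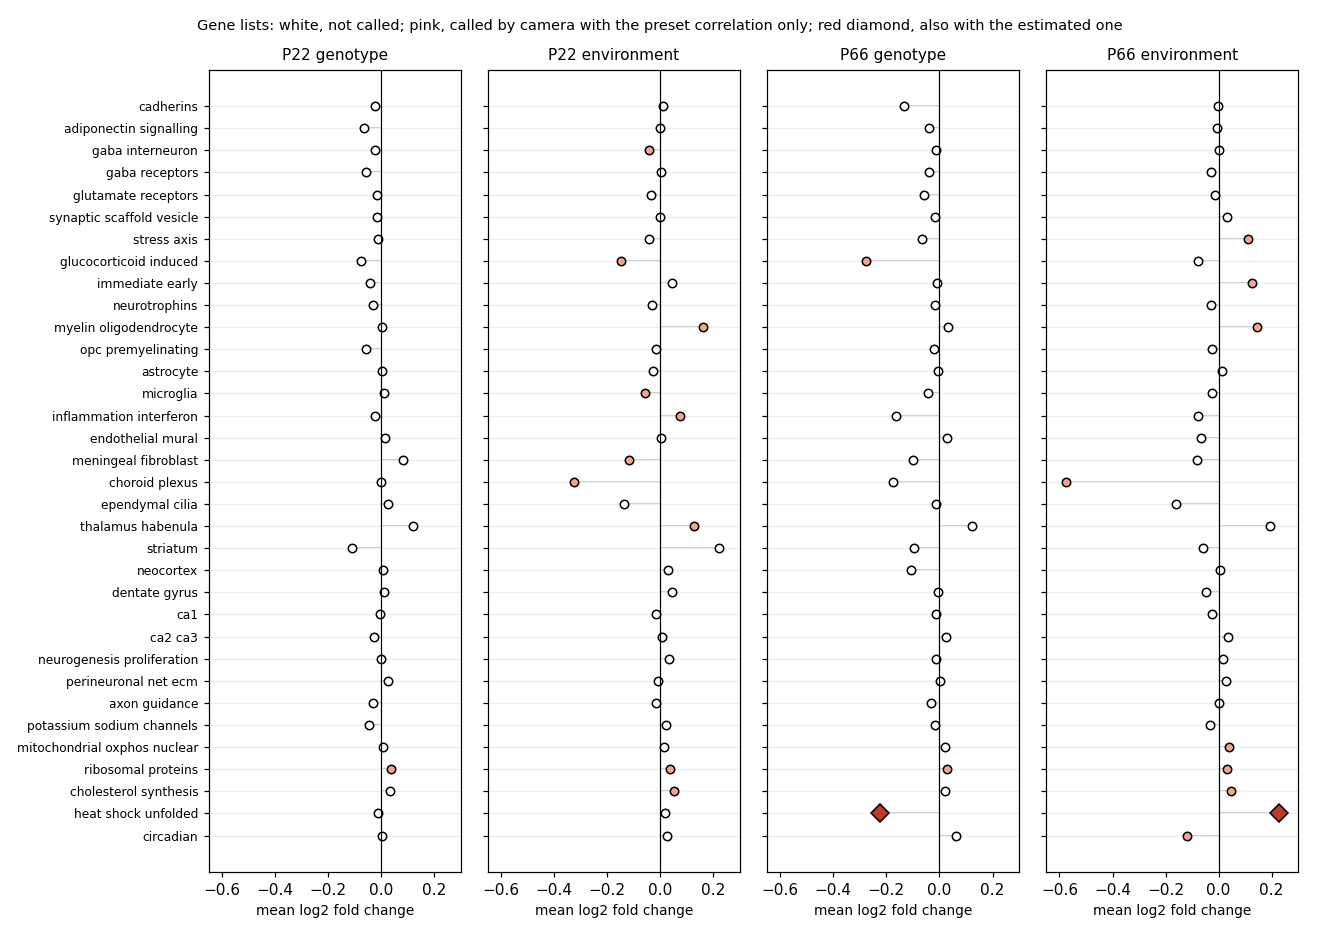
Mean log2 fold change of each of 34 gene lists for genotype and environment at P22 and P66; white points were not called, pink points were called by camera with its preset correlation, and red diamonds also with an estimated one. Only the heat-shock and unfolded-protein list is a diamond, at -0.22 for P66 genotype and 0.23 for P66 environment.

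The interaction at P66 gave no gene, and the chaperones showed both effects side by side. Hspa5 had an interaction of -0.16 (adjusted p = 0.794), with a genotype effect of -0.37 in control and -0.53 in separated animals and an environment effect of 0.53 in wildtype and 0.37 in knockout animals. Taste receptor gene Tas1r3 had the smallest p (1.5 ± 0.331, adjusted p = 0.6), ahead of Acot11 (0.37), Vangl1 (0.56), the clock gene Per3 (-0.41 ± 0.112) and Lpcat3 (0.24), each with an adjusted p = 0.794. Camera called 6 lists: ribosomal proteins (0.08, adjusted p = 7e-05), cholesterol synthesis (0.15, 0.000407), oxidative phosphorylation (0.06, 0.00501), circadian (-0.18, 0.00501), microglia (0.12, 0.00597; Olfml3 0.21, C1qb 0.22) and ependyma (0.50, 0.0281; Tmem212 0.86). With an estimated correlation the circadian list had an adjusted p = 0.167, cholesterol synthesis 0.342 and the other 4 lay between 0.683 and 0.822. By edgeR 0 genes passed and 317 had an unadjusted p under 0.05, fewer than the 350 expected without any effect. DESeq2 and limma-voom called 0.

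The same contrasts within single groups gave 0 genes by edgeR, with few by the other tools. In knockout animals at P66 the environment effect was -0.62 for Ciart (adjusted p = 0.0541) and -0.64 for Dbp, and in wildtype animals -0.30 and -0.37; the smallest adjusted p in wildtype animals was 0.218. In controls at P66 the genotype effect was 0.51 for Ciart and 0.44 for Dbp, and with an estimated correlation the heat-shock and unfolded-protein list (mean -0.22, adjusted p = 0.023) and the circadian list (mean 0.16, adjusted p = 0.0161) held. At P66, 783 genes had an unadjusted p under 0.05 for environment in knockout, 469 for environment in wildtype, 269 for genotype in control and 782 for genotype in separated animals. DESeq2 called 27, 1, 4 and 2 genes in these 4 contrasts, and limma-voom called 1 for environment in knockout animals and 0 in the others. At P22 the counts at an unadjusted p under 0.05 were 334, 463, 851 and 143 in the same order, and DESeq2 and limma-voom called 0. Without any effect 352 are expected in each contrast at P22 and 350 at P66.

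Maturation from P22 to P66 was measured in control wildtype animals as the reference for the other contrasts. Genes of young, dividing and migrating cells fell. Igfbpl1, a marker of newborn neurons, fell by 1.98 ± 0.158 on the log2 scale (SE, 7 animals at P66 against 8 at P22), Draxin by 1.2, the proliferation marker Mki67 by 1.14 and Marcksl1 by 1.03, while the stem cell factor Sox2 rose by 0.25. Of 15 tested neurogenesis genes 8 fell and 1 rose over all genes, and 10 fell and 1 rose adjusted over the list alone (mean -0.51, camera adjusted p = 1.69e-07, adjusted p = 0.00476 with an estimated correlation). Oligodendrocyte precursor genes fell in 5 of 5 members (mean -0.50; Neu4 -0.95, Itpr2 -0.42, Pdgfra -0.40, Lhfpl3 -0.39; adjusted p = 1.83e-08, and 0.000307 with an estimated correlation). A mixed list of perineuronal nets and other extracellular matrix fell in 6 of 11 genes and rose in 1 (mean -0.32, with Adamts4 -1.23, Tnc -0.81, Fn1 -0.40, Hapln2 0.73). Adjusted over the list alone 9 fell and 1 rose. That list had an adjusted p = 0.000422, and 0.0277 with an estimated correlation.

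Genes for building myelin fell as well between the ages. Ugt8a, which makes the myelin lipid galactosylceramide, fell by 1.77 ± 0.189, Cldn11 by 1.5, Gsn by 1.44 and Mal by 1.33. Of 11 myelin genes 8 fell and 1 rose over all genes, 9 and 1 adjusted over the list alone (mean -0.84, adjusted p = 1.83e-08, adjusted p = 0.244 with an estimated correlation). Cholesterol synthesis fell in 6 of 8 genes (mean -0.24; Cyp51 -0.55, Dhcr7 -0.34, Hsd17b7 -0.28; adjusted p = 0.000196, adjusted p = 0.244 with an estimated correlation). Ribosomal protein genes went both ways, 5 higher and 1 lower of 33 over all genes and 4 higher and 1 lower adjusted over the list alone (mean 0.08; Rps19 0.23, Rpl27a 0.21, Rps27 0.21, Rplp0 -0.22; adjusted p = 0.0159, adjusted p = 0.928 with an estimated correlation).

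Among the single genes named, the apelin receptor gene Aplnr fell by 2.43 ± 0.321 with age, followed by Angpt4 (-2.22), Col3a1 (-2.06), Rab7b (-2.0), Otoa (-1.77), Mkrn3 (-1.76), Mroh3 (-1.60) and Slc45a3 (-1.54), each lower in 7 of 7 animals. The ion channel gene Trpa1 rose by 1.47, Tmem184a by 1.15, Ntn5 by 1.15, Wnt16 by 1.13, BC035947 by 1.13, Tnfrsf9 by 0.99, C1rb by 0.97 and Tchh by 0.93. Lcn2, an iron-sequestering acute-phase protein gene, had the largest rise, 3.55 ± 0.717 (adjusted p = 0.000127), but only 3 of 7 animals lay above the P22 median, its level at P66 was 9.34 ± 11 CPM (SD, n = 7), and in cohort 1 it was -0.98. By edgeR 1348 of 7131 genes changed, 596 higher and 752 lower, and 452 and 568 did in cohorts 1 and 2 alone. Averaged over the 4 groups 3707 changed, 1867 higher and 1840 lower.

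**Figure D3:**
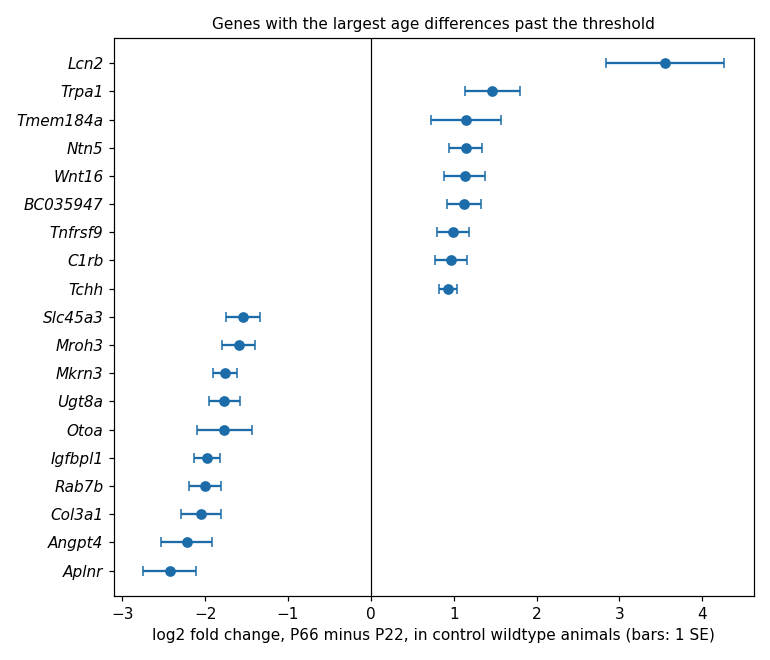
Log2 fold change from P22 to P66 in control wildtype animals (bars ± 1 SE, 7 against 8 animals) for 9 of the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold. Lcn2 stands at 3.55 with the widest error and Aplnr at -2.43.

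Whether the effects of genotype and separation differ between the ages was tested directly. The effect of separation on Ciart (-0.52), Dbp (-0.59) and Hsph1 (0.21) differed between P66 and P22 (each adjusted p = 0.0161, edgeR), and these were the 3 genes called. The heat-shock and unfolded-protein list differed by 0.22 for separation (camera adjusted p = 2.52e-09, adjusted p = 0.0152 with an estimated correlation) and by -0.21 for genotype (4.87e-10, adjusted p = 0.00971 with an estimated correlation). At P22 itself that list averaged -0.01 for genotype (adjusted p = 0.371) and 0.02 for separation (adjusted p = 0.743). Bdh2 was the 1 gene whose interaction differed between the ages (1.51, adjusted p = 0.0124); at P66 it averaged 4.60 ± 0.650 CPM (SD, n = 7) in control wildtype, 4.54 ± 0.915 (n = 10) in separated wildtype, 3.56 ± 0.724 (n = 7) in control knockout and 5.67 ± 1.23 (n = 7) in separated knockout animals. For age by genotype edgeR called 0 genes, with 153 at an unadjusted p under 0.05, fewer than the 357 expected without any effect. Within each cohort alone, age by environment and age by interaction gave 0 genes.

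Genotype effects were also compared across genes between animals that share no library. Effects in control and in separated animals had r = -0.192 and rho = -0.098 at P22 and r = 0.0314 and rho = 0.027 at P66, with 48.8% and 50.9% of genes on the same side. Between P22 and P66 r was 0.341 and rho 0.406, with 68.8% on the same side. Genes are not independent replicates, so the correlations were computed again on log2 CPM and compared with 100 regroupings of the animals. The real r on that scale was -0.2385, 0.0177 and 0.335 in the same order. Of the regroupings 17, 90 and 5, the real one included, were as large in size, so chance could not be excluded for any of the 3. Between the ages the highest other regrouping reached 0.351 on log2 CPM, where the real value was 0.335.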

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

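The gene models with a clock score as covariate were chosen only after the result was seen.

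The heat-shock and unfolded-protein list differed between the ages in its response to genotype (-0.21, P66 minus P22) and to separation (0.22), as did Hsph1 in its response to separation (0.21), and at P66 the list's score differed by 0.228 ± 0.0444 with separation (SE, 31 animals; permutation p = 1e-05, the smallest these permutations can give) and by -0.223 with knockout. Breeding cohort as the whole cause of the separation effect is argued against by the effects within cohorts. These were 0.187 in cohort 1 (95% confidence interval 0.11 to 0.263) and 0.235 in cohort 2 (0.132 to 0.338). The genotype effect was -0.0829 in cohort 1 (-0.159 to -0.00647) and -0.416 in cohort 2 (-0.519 to -0.313). These intervals do not overlap, so the size of the genotype effect differed between cohorts, and the cause was not tested. Cohort 2 held only 2 separated knockout animals at P66. Choroid plexus or oligodendrocyte content is argued against by a separation effect of 0.215 (0.115 to 0.314) with both scores in the model. Clock phase at collection stays open as a candidate explanation: with group and cohort removed, chaperone and clock scores had r = -0.467 over the 31 animals (permutation p = 0.0077, 0.0128 adjusted over 5 relations; rho = -0.488, permutation p = 0.00549; r = -0.456 and -0.492 in cohorts 1 and 2, and -0.423 without the 2 farthest animals). The clock score itself differed with separation (-0.33; -0.43 and -0.17 in cohorts 1 and 2) and with knockout (0.26, permutation p = 0.00264; 0.072 and 0.51), and with it in the model 0.605 of the separation effect (0.138 ± 0.0527, permutation p = 0.00142) and 0.687 of the genotype effect (-0.153 ± 0.0471) were left, while the calls of single genes ended: the folds of all 4 genotype genes shrank and their errors grew (Hspa5 from -0.45 ± 0.0806 to -0.32 ± 0.0871, Garem2 from 0.24 ± 0.0433 to 0.20 ± 0.0511), as did those of Hspa5 (0.45 ± 0.0814 to 0.28 ± 0.0971) and Pdia3 (0.21 ± 0.0413 to 0.11 ± 0.0471) with separation. Time of collection and an effect of separation or genotype on both gene groups cannot be told apart while the hour is unknown, and an effect of rearing or genotype on the chaperones alone stays open too.

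At P22 chaperone and clock scores had r = -0.206 (38 animals, permutation p = 0.217; rho = -0.206, permutation p = 0.214; r = -0.374 and -0.132 in cohorts 1 and 2).

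For Ciart (-0.52) and Dbp (-0.59) the difference between separated and control animals was also not the same at P66 as at P22. The hour of collection is unknown at both ages, so it cannot be told apart from a response to separation. Bdh2 differed between the ages in the interaction of genotype and separation (1.51). In both tests 4 of 100 regroupings, the real one included, gave as many genes, and 0 genes passed in each cohort alone.

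Spata5, an ATPase gene of ribosome assembly (ENSMUSG00000027722.14, chromosome 3, 37419896 to 37579096), had a median of 53.3 CPM and reached 683 CPM in separated wildtype C1-57 at P66 (others of that group up to 63.6), 425 in control wildtype C1-12 at P22 (up to 125), 117 in control wildtype C1-15 at P66 (up to 57.3) and 97.8 in separated knockout C2-23 at P22 (up to 63.9); in the separated wildtype group at P22, too large for the gap test, C2-75 had 406. Reads running in from neighbouring genes stay open, although the highest rho was 0.189 among 9 measured neighbours. A rank correlation over 69 animals responds little to the few that were high, so it cannot exclude them. Library size is argued against by r = -0.0872 (permutation p = 0.475) and rho = -0.0786 (permutation p = 0.518) with total counts. The 5 animals above 2-fold of the median had 12.1 to 13.5 M counts, within the 11.3 to 16.4 M of all libraries. Cdk8 (r = 0.977), Cd44 (0.948), Tmem56 (0.944), Camk1d (0.919) and Gpr55 (0.875) were high in the same animals, 5 genes where shuffled values gave 0, and the excess of Cdk8 was 8.06 to 9.97 times that of Spata5 in the 5 highest animals. Cells of another type may carry these genes, yet 5 partners lie below the 10 that were set for this explanation; ribosomal RNA reads also stay open, although 0 of the 6 genes share 25 bases with an annotated ribosomal RNA, because only 1 of the 354 annotated ribosomal RNA transcripts is 1000 bases or longer and introns were not searched, so that the bound set for this test was wrong. The 5 animals above 2-fold of the median were all wildtype, control wildtype C2-85 at P22 with 125 CPM among them. Separated knockout C2-23 lay at 1.83-fold. No explanation by genotype, rearing or age was tested for this pattern.

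Pdia3 was 574 CPM in separated knockout C2-63 at P22, where the other 9 animals had 438 to 509. Lcn2 was 9.5 CPM in separated knockout C1-56 at P66, where the other 6 had 0.234 to 0.781. Over 84 groups of 7 to 10 animals 6 such gaps were found, those of Spata5 included, where chance gives about 4.2, or 1 in 20. Most of the 6 were in Spata5, which was chosen after its values were seen. The count therefore cannot be judged against chance.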

How the results depend on the processing

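The clock score as covariate and leaving out libraries far from the median in choroid plexus signal were chosen only after the result was seen. Direction and side of the threshold held for 155 named genes with RLE normalization, limma-voom, the stricter filter or no cohort term. DESeq2 gave 153 and no filter 142, none reversed. Cohort 1 alone (17 of 31 animals at P66) gave 113 and 38 lost calls. Cohort 2 gave 120 and 31, composition scores 132 and 22. Many genes had no call to lose, so these counts overstate stability. Unless another reason is given, the cause was not tested.

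For P66 genotype (4 genes in the main setting) the count was 8 at an adjusted p under 0.1, 16 with DESeq2 (the same 4 among them), 0 in cohort 1, 96 in cohort 2 and 0 with the clock score. For P66 environment (26) it was 59 at an adjusted p under 0.1, 9 without a filter, 98 with DESeq2 (26 shared), 41 without the cohort term (25 shared), 0 in cohort 1, 2 in cohort 2, 4 with composition scores, 0 with the clock score and 7 without libraries far in choroid plexus signal; with the clock score 3 of the 26 are members of the score, and 25 of 26 had a smaller fold and 24 a larger error. For environment in P66 knockout animals (0) it was 8 at an adjusted p under 0.1, 27 with DESeq2, 1 with limma-voom, 8 without the cohort term, 3 with all 69 samples in 1 fit and 2 without libraries far in choroid plexus signal. Genotype in P66 controls gave 4 with DESeq2, 11 in cohort 2 and 4 with all 69 samples in 1 fit; genotype in P66 separated animals gave 2 with DESeq2 and 23 in cohort 2; environment in P66 wildtype animals gave 1 with DESeq2 and 11 in cohort 2. Age in control wildtype gave 452 in cohort 1 and 568 in cohort 2 (437 and 548 shared), and age averaged gave 2176 in cohort 1 and 1329 with composition scores (2117 and 1164 shared); the oligodendrocyte score itself falls with age, so this drop is built in. Age by genotype gave 5 in cohort 2, age by environment 0 in cohort 1 and 0 in cohort 2, and age by interaction 0 in cohort 1, 0 in cohort 2 and 0 with composition scores. Of 45 list calls in genotype, environment and interaction at each age and in age in control wildtype, 5 held with an estimated correlation. Composition scores were tried on the 38 of these calls outside the choroid plexus and myelin lists, which make up the scores; 25 calls were made there, 21 of them shared.

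Reversed in cohort 1 were Mrc1 (0.085) and Igf2 (0.044) for P22 environment, Ppp1r14a (0.075) for P22 interaction, Lcn2 for P66 genotype (0.37) and for age (-0.98). In cohort 2 they were B2m (-0.021) for P22 environment, F5 (0.11) and Steap1 (0.30) for P66 environment, and Cox6a1 (-0.14) and Rplp0 (-0.075) for P66 interaction. With composition scores it was the ribosomal protein list (-0.0052) for P66 environment; Cldn11 (-0.0061) for P22 environment and Steap1 (0.022) for P66 environment are members of the scores, which takes their change away by construction.

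Leaving out each library gave 3 (without control wildtype C2-19) to 8 (without separated wildtype C1-55) genes for P66 genotype and 3 (without control wildtype C1-6) to 75 (without separated knockout C2-84) for P66 environment, where 26 of 31 fits moved the count by over 1.5 times; without separated wildtype C1-14, C1-30, C1-55 or C1-57 or control wildtype C2-58 it was 26 to 35. Environment in P66 knockout animals ran from 0 to 17 (without separated knockout C2-53), with 10 without control knockout C1-22, 2 without control knockout C2-42 or separated knockout C2-84, and 1 without control wildtype C1-6 or C2-19, separated wildtype C1-57 or control knockout C1-30. Genotype in P66 separated and environment in P66 wildtype animals ran from 0 to 1 (without separated wildtype C1-55), and environment in P22 knockout animals from 0 to 1 (without control knockout C2-43). Age in control wildtype ran from 1175 to 1422, age averaged from 3608 to 3843, age by environment from 3 to 6 (without separated knockout C2-84 at P66; 5 without separated knockout C1-56 or control knockout C1-24 at P66, or separated wildtype C1-51 or control knockout C2-77 at P22) and age by interaction from 1 to 2 (without control wildtype C1-6 or separated knockout C1-54 at P66). The other counts stayed at 0. In all 31 fits Hspa5 and Ciart kept their call for environment and Hspa5, Pdia3 and Garem2 for genotype; Hsph1 lost its genotype call in 16, and for environment Dbp lost it in 1, Pdia3 in 6, Hsph1 in 8, Pdia4 in 15, Fbn1 in 20 and Arntl in 23. Uncalled values moved by over 1.5 times included, for P66 environment, F5 (-0.20, -0.65 and -0.56 without control knockout C1-24, separated knockout C1-58 and separated wildtype C2-64) and Steap1 (-0.16, -0.52 and -0.52 without control knockout C1-24, separated knockout C1-58 and separated knockout C2-53), and for P22 environment F5 (-0.31) and Slc13a4 (-0.13) without control wildtype C1-32, Nexn (0.19) without separated wildtype C1-1 and B2m (0.042) without separated wildtype C1-29; for P22 interaction Trh went to 1.47 without control wildtype C1-32, and for P66 interaction Cox6a1 to 0.083 without separated knockout C1-56. Comparing genotype effects without Cdh13 and its neighbours was not run, since these genes were not analysed here. At this depth and group size edgeR recovered 61.2% of genes changed 1.2-fold and 91.0% of those changed 1.5-fold for P66 environment in simulated data.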

Other observations

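The test of the choroid plexus pattern was chosen only after the result was seen. Between the ages, averaged over the 4 groups, meningeal genes fell in 5 of 8 members and none rose (mean -0.56, camera adjusted p = 0.0238, adjusted p = 0.749 with an estimated correlation). Cholesterol synthesis genes fell in 7 of 8 (mean -0.30, adjusted p = 1.78e-06, adjusted p = 0.0727 with an estimated correlation) and myelin genes in 10 of 11 with 1 higher (mean -0.96, adjusted p = 8.47e-09, adjusted p = 0.202 with an estimated correlation). Neurogenesis genes (12 of 15 lower, 1 higher) had a camera adjusted p = 0.0133 with an estimated correlation. By the same test oligodendrocyte precursor genes (5 of 5 lower) had 0.00364. The mixed list of perineuronal nets and other extracellular matrix (9 of 11 lower, 1 higher) had 0.028. Potassium and sodium channel genes rose in 8 of 17 members and fell in none, but the list was not called (mean 0.08, adjusted p = 0.062).

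Between animals of 1 group, ribosomal protein genes and glutamate receptor genes ran in opposite directions. This pair of lists was not among the comparisons fixed beforehand, and its p-values do not allow for that choice. The cause was not tested. With group and cohort removed their scores had r = -0.567 at P22 (38 animals, permutation p = 0.00012, 0.0003 adjusted over 5 relations; rho = -0.495, permutation p = 0.0016) and r = -0.690 at P66 (31 animals, permutation p = 4e-05, 0.0002 adjusted; rho = -0.604, permutation p = 0.0005). In cohorts 1 and 2 r was -0.484 and -0.639 at P22 and -0.686 and -0.750 at P66, and without the 2 farthest animals -0.514 and -0.495.

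Choroid plexus genes were lower in separated than in control knockout animals at P22, by a mean log2 change of -1.03, and ependymal genes by -0.50, while in wildtype animals the means were 0.38 and 0.23. Choroid plexus tissue carried along in single dissections is a candidate explanation: residuals of the 11 members correlated at 0.923 between animals on average. The score differed by -1.04 between the 9 control and 10 separated knockout animals (exact permutation test within cohort over 19305 splits, two-sided p = 0.0656), and single animals ran from 2.38 to 5.95 and from 2.2 to 5.79. An effect of separation on the tissue itself was not tested.

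A hypothesis that genotype and separation shift genes in opposite directions at P66 across all genes was tested and not borne out. The correlation of both effects across genes was 0.0165, and 23 of 100 regroupings were as low. With the clock score in the model it was -0.151, and 5 of 100 were as low. Since there was no opposition without the score, this says nothing on clock phase as its cause.

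Regroupings shuffle single animals and take littermates as independent, which the labels used here do not allow to check. Each contrast is also taken by itself here, without adjustment over the contrasts. On these conditions chance can be excluded at 0.05 for the count of genes with age in control wildtype animals (1348 genes, 1 of 100 regroupings with as many, highest other 1). It can also be excluded for age averaged (3707, 1 of 100, highest other 33). Genotype at P66 had 1 of 100 as well, the smallest share these regroupings can give. Its 4 genes lay close to the highest other count of 2. Shares nearer to 0.05 came for separation at P66 (26 genes, 3 of 100, highest other 1202), age by environment (3, 4 of 100, highest other 65) and age by interaction (1, 4 of 100, highest other 1). With this many contrasts such shares can arise by chance, so chance is not excluded for them or for genotype at P66. For separation at P66 regroupings with 1202 and 93 genes, several times the real count, point to a structure of the samples beside the groups; what it follows was not settled. For the contrasts with 0 genes every regrouping, 100 of 100, necessarily has at least as many, so this count says nothing about chance there. Their highest other counts at P22 were 1 for genotype, 1 for environment, 8 for the interaction, 130 and 0 for genotype in control and separated animals, and 219 and 46 for environment in wildtype and knockout animals. At P66 they were 24 for the interaction, 29 and 26 for genotype in control and separated animals, and 1669 and 391 for environment in wildtype and knockout animals. For age by genotype it was 13.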
